A study of Rattus norvegicus with 8 samples.

How the data were processed

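Liver RNA of 8 Wistar rats fed a high-fat diet for 16 weeks was measured on 8 spotted 2-colour arrays, 1 rat per array. Per the labels, 4 rats were obesity-prone (OP) and 4 obesity-resistant (OR). On every array the rat's RNA carried the dye Cy3 and a pool of 4 chow-fed control rats carried Cy5, with no dye swap. Both RNAs were amplified as aminoallyl cRNA before the dyes were coupled.

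The deposited scanner files hold the intensity of each spot and of its surrounding background, 1 file per channel, 16 files in all. Per the file headers they were quantified with ImaGene using fixed circles, and the intensities are neither background-subtracted nor normalized. The header version is 5.1, whereas the series text names ImaGene 4.2, and that text names 2 different scanners. Each array has 12288 spots in 48 blocks. The deposited value table holds, per the series text, a background-subtracted and LOWESS-normalized log ratio by the authors. The log base and the rule for missing values are not given in the sources used here. Column medians of that table lay between -0.0065 (OR rat 4) and 0.033 (OP rat 4), with 0.0033 for OP rat 1, 0.021 for OP rat 2, 0.011 for OP rat 3, -0.0010 for OR rat 1, 0.0060 for OR rat 2 and 0.010 for OR rat 3.

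The direction of the deposited log ratios was checked against the scanner files. Rows were matched to spots by the values of 7 arrays, where the nearest spot was less than 0.5 times as far as the second nearest, and the array left out was then compared. In the 8 such comparisons, over 1343 to 2484 matched rows, the deposited value correlated with log2(Cy3/Cy5) at r between -0.998 and -0.983. The scanner ratio was log2 of the background-subtracted signal medians after a lowess fit with span 0.3. When the opposite sign was used for the match, at most 76 of 9109 complete rows matched. The deposited values thus follow Cy5 over Cy3 of the files, although the series text states green over red. The slope on the scanner ratio ran from -0.742 to -1.35. The deposited values were used as if on a log2 scale, but their base is unknown and a scale factor that differs between arrays stays unexplained, so their sizes are uncertain. Throughout, the ratio is Cy3 over Cy5 (rat over pool), as the dyes are labelled, and the sign of the deposited values was turned wherever they were used.

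The main values came from the scanner intensities. Signal means and background medians were corrected with normexp and an offset of 50, and log2(Cy3/Cy5) was normalized within each array by global loess in limma 3.58.1 (R 4.3.3). Spots with the manual flag 1 were set missing (447 values, 0.455%). Spots with the empty-spot flag 2 were kept. A channel was called detected where the signal mean exceeded the background mean by 2 background SDs. A probe was tested where Cy3 was detected on every array of at least 1 group or Cy5 on at least 0.5 of the arrays, with at least 3 values per group. This left 11362 probes, and 926 spots were left out. No spot is marked as a control in the files, so none was left out or given weight 0 on that ground. Each spot was counted as 1 probe, and repeated spots could not be averaged as planned. Control or repeated spots may therefore be among the tested probes, and counts of probes are not counts of distinct transcripts.

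The files do not pair spots or table rows with genes. Scanner files give each spot's grid position, and the value table gives row IDs that could not be joined to the RefSeq gene table of assembly GRCr8 used here (0 matched). The gene lists fixed beforehand and the test of them were therefore not run, and spots are named by position. The plan had stated that the authors' table would take the place of the scanner values where no probe identity could be matched to a gene. That table names no gene either, so the scanner values were kept, a choice made before any group was tested, and counts from the authors' table stand beside the main counts.

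OP and OR were compared with each other and each with the pool, 3 comparisons in 1 limma model (lmFit and eBayes, Benjamini-Hochberg adjustment over all tested probes) with 6 residual degrees of freedom and 2.75 prior degrees of freedom. A probe was called at an adjusted p under 0.05. The pool cancels in OP minus OR. Against the pool, the mean ratio was tested against 0. That test leaves out the spread between control rats, since the pool is 1 control sample, and any dye effect of a probe stays in the ratio. Spots were named by a rule set before the data were examined. It took, against the pool, the largest changes past the threshold with the same sign on all 4 arrays, and, for OP against OR, the smallest p where none passed. With no gene names, only 2 spots per direction and comparison are given. Measures with 1 value per array were compared by exact two-sided permutation of the 70 assignments.

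The fit was tested on simulated data with independent normal noise, at each probe's residual spread as moderated by eBayes. For OP against OR, 78% of probes changed 1.5-fold were called. So were 96% of those changed 2-fold and 100% of those changed 3-fold or 4-fold, with 10 false calls among the unchanged of 11362 probes. For OP against the pool, the shares were 96%, 96%, 100% and 100%, with 7 false calls. No error shared between arrays, such as that of the pool, the dyes or the slides, was simulated. These shares and false calls therefore cannot vouch for the tests on the real arrays, least of all those against the pool. The number of arrays limits the precision.

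Alternatives set before the data were examined were other background corrections, an offset of 0, median centring, print-tip loess, Aquantile, the authors' values, other filters, other uses of flags, signal medians, array weights, eBayes with trend and robust settings, a replicate block, the Cy3 channel alone, each group alone, a 1.5-fold minimum and the omission of each rat. Alternatives chosen after seeing the data were the day of image quantification (as a block, as a random block and within a day), the run of slide numbers as a random block, and the rows of the authors' table whose IDs begin with rn. For the day, only its month and day were compared, because the year of the header clock differs between arrays. For the slide runs, the numbers that the images carry were sorted, and a large gap started another run. The size of that gap was also set after seeing the data. The labels name no runs, so the runs are inferred. Python 3.11.15 with scipy 1.17.1 and statsmodels 0.14.6 was used for matching rows.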

Results

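The series asked how liver transcripts differ between rats prone to obesity on a high-fat diet (obesity-prone, OP) and rats resistant to it (obesity-resistant, OR). Livers of 4 OP and 4 OR Wistar rats were profiled after 16 weeks, each rat on its own array against one pool of 4 chow-fed rats. Ratios are given as log2(Cy3/Cy5), rat over pool, as the dyes are labelled, so a positive value is higher in the rat. The authors' deposited values run the other way, against the direction stated for them. If the rat had been in Cy5, higher and lower would swap throughout.

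Signal stood above background at most spots. The share of the 12288 spots detected in Cy3 was 93.2% ± 3.8 (SD, n = 4) on OP arrays and 89.8% ± 2.8 (SD, n = 4) on OR arrays (exact permutation p = 0.20, adjusted p = 0.32 over 7 measures). In Cy5, which held the same pool on every array, it was 91.9% ± 2.0 on OP arrays and 85.9% ± 4.6 on OR arrays (n = 4 each, exact permutation p = 0.0857, adjusted p = 0.20). Before normalization the median log2 ratio was -0.88 ± 0.12 on OP arrays and -0.70 ± 0.06 on OR arrays (SD, n = 4 each, exact permutation p = 0.0571, adjusted p = 0.20). The median Cy5 background was 94 ± 10.6 on OP arrays and 136.5 ± 34.1 on OR arrays (SD, n = 4 each, exact permutation p = 0.0857, adjusted p = 0.20). With 70 assignments the smallest exact p is 0.0286, so a single differing measure among the 7 compared could reach no adjusted p below 0.20, and these tests do not show that the arrays were alike.

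The array profiles of OP rats resembled one another more than those of OR rats did. All 4 OP arrays fall in 1 run of slide numbers, inferred from the number each image carries, and that run holds no OR array. Likeness of the livers and likeness of the slides therefore cannot be told apart. Pearson's r across 11362 probes, which are not independent replicates, averaged 0.620 (range 0.553 to 0.704) between OP rats and 0.334 (0.255 to 0.412) between OR rats. Between an OP and an OR rat it averaged 0.321 (0.249 to 0.407). The difference of 0.286 between the OP and OR averages had an exact two-sided permutation p of 0.0286, the smallest that 70 assignments allow. With OR rat 1, 2, 3 or 4 left out, the difference was 0.297, 0.288, 0.278 and 0.263, with exact permutation p of 0.0571, 0.0857, 0.0571 and 0.114.

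**Figure D1:**
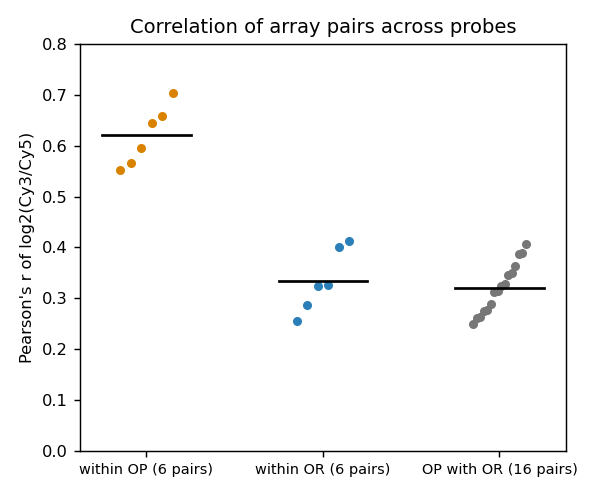
Pearson's r of log2(Cy3/Cy5) across probes for each pair of arrays, by pair class, with the class mean as a line. The 6 OP pairs (0.553 to 0.704) lie above all 6 OR pairs (0.255 to 0.412) and all 16 mixed pairs (0.249 to 0.407).

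The direct comparison of OP with OR, in which the pool cancels, asked which transcripts separate the phenotypes on one diet. No probe of 11362 passed an adjusted p of 0.05 in limma. The smallest adjusted p was 0.0557, shared by 45 probes, and 698 probes lay under 0.1. At an unadjusted p under 0.05 there were 2285 probes, 1159 higher and 1126 lower in OP, where 568 are expected by chance. The Cy5 channel alone, labelled as the same pool on every array, gave 945 (0 at an adjusted p under 0.05). Technical differences between the OP and OR arrays are therefore not excluded. The values of the 4 OP rats did not overlap those of the 4 OR rats at 1647 of 11071 complete probes, or 14.9%, where chance gives 2.86%.

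The spots with the smallest p had modest differences. Spot Sr10Sc01R03C16 read 0.61 ± 0.10 in OP and 0.05 ± 0.02 in OR (log2 ratio to the pool, SD, n = 4 each, limma adjusted p = 0.0557). Spot Sr08Sc03R11C06 read 0.53 ± 0.07 in OP and -0.06 ± 0.11 in OR. In the other direction, spot Sr02Sc01R16C03 read -0.46 ± 0.11 in OP and 0.19 ± 0.10 in OR, and spot Sr06Sc01R11C10 read -0.40 ± 0.04 and 0.07 ± 0.08. All 4 share the adjusted p of 0.0557. The files do not pair these positions with genes.

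The count of 0 lay close to the threshold and changed with the processing. It became 653 (113 higher, 540 lower) with median centring in place of loess and 531 (356 higher, 175 lower) without OP rat 3. Among 8700 probes detected in both channels of all arrays it was 459 (163 higher, 296 lower). Leaving out all flagged spots gave 68, the Cy3 channel alone 56 and print-tip loess 46. The authors' values gave 2 of 10111 rows. At an unadjusted p, the split under median centring was 1003 higher and 1514 lower. Images were quantified on 3 days, the first with 2 OP arrays, the second with 2 OP and 1 OR and the third with 3 OR. With the day as a block, the difference is estimated from the second day alone, which holds 1 OR array. In that fit 14 probes (0 higher, 14 lower) had an adjusted p under 0.05 and 1735 an unadjusted p under 0.05, values that rest on OR rat 1. As a random block, the counts were 235 and 2615, at an estimated within-day correlation of -0.114. Within the second day, 0 of 11334 passed in limma and 1246 had an unadjusted p under 0.05, with the lone OR array assumed to vary like the OP arrays. The slide numbers of the OP arrays form 1 run and those of the OR arrays 2 others. With the run as a random block, 0 passed in limma and 2082 had an unadjusted p under 0.05. No run holds both groups, so this block cannot remove a run effect from OP minus OR.

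**Figure D2:**
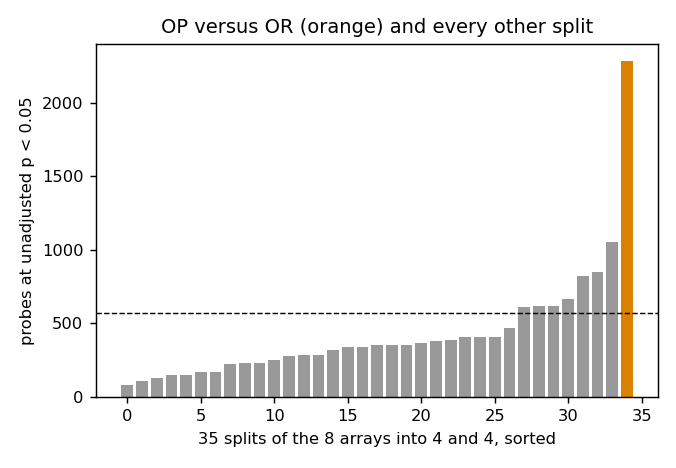
Number of probes at an unadjusted limma p under 0.05 for each of the 35 splits of the 8 arrays into 4 and 4, sorted by count, with the number expected by chance (568) as a dashed line. The split into OP and OR (orange) gives 2285 and the next highest split gives 1050.

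Against the chow pool, OP livers differed at 4344 of 11362 probes (38.2%), 2132 higher and 2212 lower. Most differences were small, with a median absolute log2 ratio of 0.28 among the called probes. Of the called probes, 370 differed at least 1.5-fold (209 higher, 161 lower) and 19 at least 2-fold. The highest was spot Sr12Sc03R05C02, 3.90-fold above the pool (log2 1.96 ± 0.28 SD, n = 4, limma adjusted p = 0.000101). Spot Sr02Sc04R14C10 was 2.73-fold above it (1.45 ± 0.07, adjusted p = 4.15e-05). The lowest were Sr03Sc02R11C09 (log2 -1.47 ± 0.44, limma adjusted p = 0.000986) and Sr10Sc03R08C15 (-1.40 ± 0.38, adjusted p = 0.000873). All 4 spots were detected in both channels of every array. The pool is 1 control sample and every rat was in Cy3, so the spread between control rats is left out of these tests and dye effects are not removed. With median centring in place of loess the count was 6101 (2621 higher, 3480 lower). Without OP rat 4 it was 2766, and the authors' values gave 3383 of 10111 rows (1529 higher, 1854 lower).

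OR livers differed from the pool at 2290 of 11362 probes (20.2%), 1117 higher and 1173 lower, under the same limits. The median absolute log2 ratio among them was 0.25, and 90 differed at least 1.5-fold (40 higher, 50 lower) and 16 at least 2-fold. Spot Sr03Sc04R13C06 was 3.21-fold above the pool, with a wide spread (log2 1.68 ± 1.20 SD, n = 4, limma adjusted p = 0.0176), and lost its call without OR rat 2 (limma adjusted p = 0.0599) or OR rat 3 (limma adjusted p = 0.062). Spot Sr10Sc01R04C07 was 2.99-fold above it (1.58 ± 0.57, adjusted p = 0.00455). Spot Sr03Sc02R11C09, also among the lowest in OP, read -1.54 ± 0.36 (limma adjusted p = 0.00272, n = 4), and Sr06Sc01R04C02 read -1.35 ± 0.45 (adjusted p = 0.00516). The count depended on single rats. It was 1430 without OR rat 1, 1053 without OR rat 2 and 1338 without OR rat 3. A fit of the OR arrays alone gave 1002 of 11077 probes, whereas a fit of the OP arrays alone gave 4467 of 11547 against the pool. The authors' values gave 2721 rows for OR (1300 higher, 1421 lower).

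Both groups moved alike at 1504 probes, 764 higher and 740 lower than the pool in each, and in opposite directions at 17. Independent lists of these sizes would share 209.6 higher and 228.4 lower probes and would hold 437.6 in opposite directions. Simulated unchanged groups with a shared pool gave on average 0.35 probes higher in both and 0.05 lower in both. Those groups held on average only 5.6 calls in OP and 5.7 in OR, against 4344 and 2290 observed. Their overlap was thus bound to be near 0, and it is no measure of how far OP and OR respond alike. The mean ratios of OP and OR had a covariance of 0.0254, against 0.00829 in the simulation, and a correlation across probes of 0.527, against 0.501. The pool cannot be split, so part of the excess over independent lists may come from the shared pool, and dye effects, which both groups share, were not simulated. The shared count was 731 without OR rat 2 and 975 without OR rat 3. With median centring it was 2268, of which 924 were higher and 1344 lower.

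A further 2823 probes passed against the pool in OP alone and 769 in OR alone. Since no probe passed the direct test of OP against OR, these counts do not show which probes differ between the groups.

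**Figure D3:**
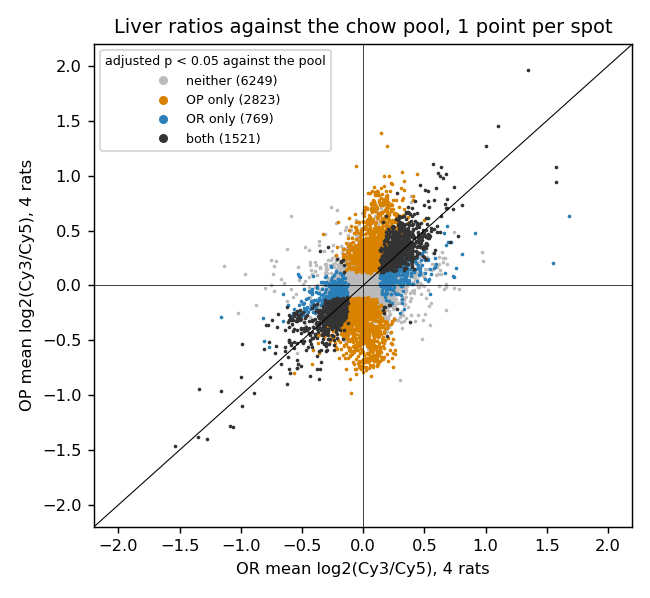
Mean log2(Cy3/Cy5) of 4 OP rats (vertical) against that of 4 OR rats (horizontal), 1 point per probe, coloured by which groups passed an adjusted p of 0.05 against the pool, with the line of equality. Of 11362 probes, 2823 passed in OP alone, 769 in OR alone and 1504 in both with one sign. The points coloured as both also include the 17 that passed in both with opposite signs.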

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

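The restriction to probes detected on all arrays and the Cy3 channel alone were set before the data were examined as alternatives. Their use as tests of explanations, and the other tests given here except the count of splits for the calls against the pool, were chosen after the result was seen.

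The deposited ratios run against the direction stated for them: in each array left out of the matching, they correlated with log2(Cy3/Cy5) at -0.983 or lower. A table written as pool over rat may account for this and would leave the dyes as labelled. Exchanged names of the channels would give the same correlation but place the rats in the channel named Cy5. Taken alone, the Cy3 channel held 686 more group differences at an unadjusted p under 0.05 than the Cy5 channel (1631 against 945), and the highest of the other 34 splits gave 278 more, which argues against exchanged names. That stays open, because slide run follows group and a run effect in one dye would look alike. The variance within groups averaged 0.0828 in Cy3 and 0.0883 in Cy5 (exact paired permutation p = 0.359). Cy3 was the more variable channel on 3 of the 8 arrays. With 8 arrays this test cannot show that the channels varied alike, and its values do not favour the dyes as labelled.

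OP and OR differed at 2285 probes at an unadjusted p under 0.05. Of the 35 splits of the arrays, 1 (the real one) gave as many, the highest other giving 1050. This argues against chance assignment of the rats as the source but, with only 35 splits, cannot exclude it. Dim probes as the whole cause are argued against by the 8700 probes detected in both channels of all arrays, of which 23.8% (2068) passed, against 946 in the highest other split. The run of slides and the group cannot be told apart, since no run holds both groups, and 2082 probes had an unadjusted p under 0.05 with the run as a random block. A difference between the phenotypes is among the open explanations, untested apart from the run.

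OP arrays resembled each other more than OR arrays, with mean correlations 0.286 apart, and 1 of 35 splits (the real one) gave as large a difference, the highest other being 0.169. Noise at dim spots of OR arrays as the whole cause is argued against by the probes detected on all arrays, where the residual variances were 0.0317 in OP and 0.0312 in OR and the difference was still 0.197, with the smallest exact p (0.0286). The covariance within OP exceeded that between groups by 0.029 (jackknife SE 0.013 over 8 arrays), whereas that within OR differed from it by -0.0010 (SE 0.0037). A component shared by OP livers and a component shared by the 1 run of slides that holds all OP arrays cannot be told apart, because no OR array lies in that run.

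The splits cannot test the count of 0 probes past an adjusted p of 0.05 in limma (2285 at an unadjusted p under 0.05), because any split gives at least 0. All 35, the real one included, gave 0. The 2054 more calls against the pool in OP than in OR were matched by 2 of the 35 splits, the real one included, the highest other being 2127, so chance is not excluded for that difference.

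In 8 of 44 groups of 4 values, 1 array lay far from the other 3 (a gap above Dixon's 95% critical value). The measures are linked and the spots were picked from these data, so this share cannot be set against a chance rate. OP rat 1 had a median Cy3 signal of 347 (other OP arrays up to 260.4) and a median Cy3 background of 171 (other OP arrays up to 89). On OR arrays the median Cy3 signal reached 363.6 (OR rat 4) and the median Cy3 background 101 (OR rat 4). OP rat 2 had 94 manually flagged spots against at most 17 on the other OP arrays. OR rat 4 had a median Cy5 signal of 616 against at most 486.2 on the other OR arrays. At spot Sr02Sc01R16C03, OP rat 4 read -0.6157 (nearest other OP rat -0.4215) and OR rat 1 read 0.3438 (nearest other OR rat 0.1508). OP rat 3 read -0.8033 at Sr03Sc02R11C09 (nearest other OP rat -1.635) and -0.6724 at Sr06Sc01R04C02 (nearest other OP rat -1.586).

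All 4 OP rats lay below the pool and all 4 OR rats above it at Sr02Sc01R16C03 (OP minus OR -0.6517 on the log2 scale) and at Sr06Sc01R11C10 (-0.4695), both with a limma adjusted p of 0.0557. Such opposite sides occurred at 249 probes, against 63 in the highest other split.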

How the results depend on the processing

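The day, slide-run and rn-row settings were chosen after seeing the data. Probes past the threshold between OP and OR, 0 in limma as reported (2285 unadjusted), numbered 653 with median centring, 459 in probes detected on all arrays, 235 with day as a random block, 68 with all flagged spots left out, 56 in Cy3 alone, 46 with print-tip loess, 14 with day as a block and 2 in the authors' values and in their rn rows. The cause was not tested. Every other setting run gave 0, and leaving out 1 rat gave 0 to 531. The unadjusted count was 1246 within the second day, which has 3 arrays, and 1777 to 2249 with 1 rat left out. Calls against the pool were 370 in OP and 90 in OR at 1.5-fold or more, 2747 of 8630 in OP in the rn rows of the authors' values (3383 of 10111 in all their rows), and 1002 in OR arrays alone. The cause of the last 2 was not tested. With 1 rat left out they were 2766 to 4505 in OP and 1053 to 2137 in OR. The shared count was 2268 with median centring (cause not tested) and 731 to 1239 with 1 rat left out. The difference in mean correlation ran from 0.255 to 0.334 with 1 rat left out. Aquantile leaves log ratios as they are, so it tests nothing here. Same-numbered OP and OR rats deviated together at r of 0.191, -0.063, 0.078 and 0.032. The labels do not say whether the numbers pair rats, and these values cannot settle it. With the replicate block, 0 probes passed in limma and 2329 had an unadjusted p under 0.05, and not every rat correlated best with its own number. For the named spots, 249 values kept direction and side of the threshold, 25 (all OP against OR) newly passed, 2 (Sr03Sc04R13C06 in OR) no longer did and none reversed. Many could not reverse. Filters, Aquantile and, against the pool, leaving out a rat of the other group do not alter a spot's mean ratio. The spots were also picked from these data, so the tally is no measure of robustness. Gene lists and their camera, fry and probe-mean alternatives were not run, for want of gene names. Signal over background limits dim spots: 80.9% (OR rat 3) to 94.3% (OP rat 2) of spots were detected in Cy5.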

Other observations

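In the authors' values with the sign turned, 2 rows passed an adjusted p of 0.05 between OP and OR in limma, named here after their values were seen. Row rn3532 read -0.93 in OP and -1.64 in OR (the authors' log ratio, of unknown base and scale, n = 4 each, limma adjusted p = 0.012), and row rn5394 read 0.04 in OP and 0.93 in OR (limma adjusted p = 0.0236). The files do not pair these rows with genes. At an unadjusted p under 0.05 there were 2049 rows.

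The value table holds 10200 row IDs that begin with rn and 2088 that begin with c, a difference the sources used here do not explain. Values were missing at 10.9% of the former and 24.5% of the latter.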
